A study of Canis lupus familiaris with 6 samples.

How the data were processed

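The series holds polyA RNA-seq of HU-HSA-2, a canine hemangiosarcoma cell line, in 6 libraries. Per the labels, 3 libraries are controls and 3 come from cells given (R)-GNE-140, an inhibitor of the lactate dehydrogenases LDHA and LDHB. Per the labels' protocols, cells received DMSO or the compound for 72 hours, and the libraries were made with a directional kit. No dose is given in the sources used here.

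The deposited values are TPM, a transcript abundance that the authors scaled to a fixed total per library. Per the submitters' processing notes the tools were STAR, RSEM and edgeR 3.42.0, and their order and settings are not given in the sources used here. The genome build is likewise not given in the sources used here, so no coordinates are printed. The TPM values are rounded to 2 decimals and have the same sum in each library within rounding. TPM keeps no read depth, so the depth of each library is unknown, no count test was run and no counting interval is given. The precision of a value is therefore judged only from the spread between the 3 libraries of a group.

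The table has 20500 rows, of which 18315 carry a symbol and 2185 carry an Ensembl identifier. A separate list of identifiers and symbols in the same table was used to find the identifier of a symbol. Of the symbols, 17532 matched the RefSeq gene table of the assembly UU_Cfam_GSD_1.0, which was used for names. 233 rows share 111 symbols with another row, and these were left out of the gene lists. 5321 rows were 0 in all 6 libraries, and 738 rows above 0 repeated the 6 rounded values of an earlier row. Leaving these repeats out lowered the genes tested only from 10874 to 10869, so nearly all had a mean TPM under 1. At that level rounded values can be equal by coincidence. Repeated values at higher TPM are not taken as separate measurements. Near-identical copies can share reads in an estimate of this kind, and their values are uncertain. LDHA and the mitochondrially encoded genes matched no row name and are not analysed here.

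Genes with a mean TPM of at least 1 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with group as the only term, moderated variances with a mean trend, 2-sided tests and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this log2(TPM + 1) scale, which understates the change of genes at low TPM. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

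The 39 gene lists, the tests, the named-gene rule and most alternatives were fixed before the data were examined. Of 932 list memberships, 842 matched a row. Lists with at least 3 tested members were compared with all other genes by limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists tested. Camera was repeated with an estimated correlation between genes. In limma this form also has few degrees of freedom at 3 against 3 libraries, so it loses calls more easily. Fry was also run, whose PValue tests whether a list's genes move, on balance, in 1 direction and does not compare them with other genes. Each list's members were counted after adjustment over all genes and after adjustment over the list alone.

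Named genes were chosen by this rule, for genes with a symbol. LDHA, LDHB and LDHC were to be named always. The 10 risen and 10 fallen genes with the largest log2 fold change were taken among those past an adjusted p of 0.05, with a mean TPM of at least 5 in the higher group and no overlap between the groups. Up to 4 members with the smallest limma p were taken from each list past its camera threshold and from the 5 main lists. The main lists were cholesterol synthesis, cholesterol uptake and SREBP regulation, fatty acid synthesis, glycolysis, and lactate and pyruvate handling. Genes named outside the rule were chosen after their values were seen, and are marked so. Some genes picked by the rule are not reported here.

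The steps were tested on simulated data made from the real means and spreads, with 200 changed genes in each of 20 simulations of the 3 against 3 comparison (a median of 10817 genes tested). The limma test recovered 26.9% of genes changed by a log2 of 0.3, 58.6% at 0.5 and 89.6% at 1, with 4.71% false calls, and camera called 0 of 700 random lists. Noise was drawn independently for each gene. The 0 of 700 therefore cannot show how often camera falsely calls lists of correlated genes. Alternatives covered the pseudocount (0.1 and 5), the filter (none, and a mean TPM of at least 5), 3 other scalings, the variance model, a replicate block and each library left out in turn. A further alternative, leaving out rows with repeated values, was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.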

Results

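Gene expression was measured in HU-HSA-2, a cell line from canine hemangiosarcoma, a malignant tumour of blood vessel cells. There were 3 control libraries and 3 libraries after (R)-GNE-140, a small molecule that inhibits lactate dehydrogenase, the enzyme that interconverts pyruvate and lactate. Between 13379 and 13861 genes had a TPM above 0 in a library, and 10755 to 10970 had a TPM of at least 1. The 20 most abundant genes took 14.6% to 17.0% of the TPM of a library. The depth of the libraries is unknown. Libraries of a group correlated at r = 0.990 to 0.993 across genes, and libraries of different groups at 0.987 to 0.991, where genes are not independent replicates. The first principal component, with 34% of the variance, placed all 3 controls on one side and all 3 treated libraries on the other.

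The series title names lactate dehydrogenase and cholesterol and lipid metabolism, and the comparison of treated with control cells asks which transcripts differ when the enzyme is inhibited. In the cholesterol synthesis and fatty acid synthesis lists, 6 of 19 and 5 of 22 tested genes fell and 0 rose, and both lists were called lower by camera at the preset correlation but not with an estimated one. Of 10874 genes tested, 329 (3.03%) changed (limma, Benjamini-Hochberg), 142 higher and 187 lower. At an unadjusted limma p under 0.05 there were 1947, and unadjusted counts in the lists below are to be read against that share. The changes were small, with a median absolute log2 fold change of 0.38 among the 329, and 15 genes reached an absolute log2 of 1 (12 higher, 3 lower), against 28 on log2(TPM + 0.1) and 6 on log2(TPM + 5). In 23.1% of tested genes the 3 treated values lay apart from the 3 control values, where chance gives 10%. Leaving out a library lowered the count to 92, 185 and 167 without control replicates 1, 2 and 3, and to 152, 122 and 74 without (R)-GNE-140 replicates 1, 2 and 3. It was 168 without the filter on low values and 159 without the variance trend, where 57.9% of the changed genes were higher against 43.2% here.

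LDHB (ENSCAFG00845014696), a target of the compound, was at 969 ± 29.1 TPM in controls and 969 ± 28.2 TPM after treatment (SD, n = 3 each). An inhibitor acts on the protein, so the transcript level does not check the labels. The log2 difference was -0.0009 with a 95% interval of -0.0963 to 0.0946 (limma adjusted p = 0.993), and an exact 2-sided permutation test gave p = 1, where the smallest possible is 0.1. The sign of this difference turned under quantile normalization (0.0604) and with the 20 most abundant genes removed (0.0109). It also turned without control replicate 3 (0.0239) and without (R)-GNE-140 replicate 1 (0.0233). LDHC was listed at 0 in all 6 libraries. LDHA is not analysed here.

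The cholesterol synthesis list was called lower after (R)-GNE-140. Of 19 tested enzymes, 6 fell, 0 rose and 13 did not pass, while 13 fell when adjusted over the list alone. SQLE (ENSCAFG00845012036), the squalene epoxidase, fell from 42.7 ± 0.451 to 27.6 ± 1.51 TPM (log2 -0.61, SE 0.06, limma adjusted p = 0.00271). MSMO1 (log2 -0.44) and CYP51A1 (log2 -0.36), both sterol demethylation enzymes, fell as well. The list median was -0.236 and the list was lower than other genes (camera, Benjamini-Hochberg adjusted p = 2.47e-09), with adjusted p = 0.367 with an estimated correlation.

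**Figure D1:**
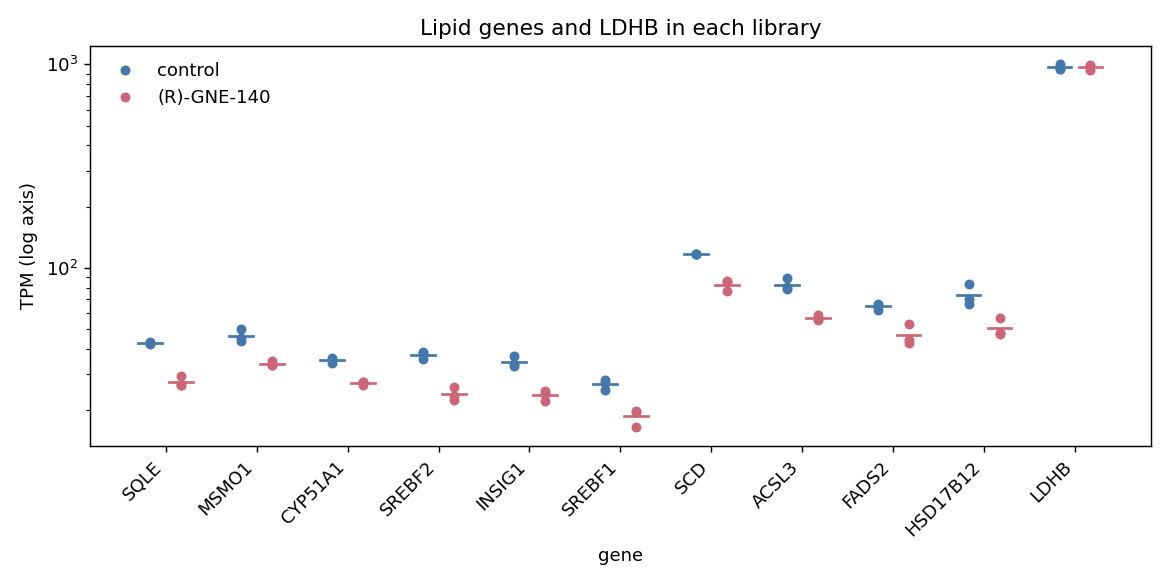
TPM (log axis) of the named lipid genes and LDHB in each library, with points for the 3 control and 3 (R)-GNE-140 libraries and lines at the group means. SQLE fell from a mean of 42.7 to 27.6 TPM, while LDHB was at 969 TPM in both groups.

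Regulators of cholesterol uptake and of the SREBP transcription factors, which switch on sterol and fatty acid genes, were called lower as a list. Of 14 tested members, 4 fell, 0 rose and 10 did not pass, and 10 fell when adjusted over the list alone. SREBF2 (ENSCAFG00845015666), the main SREBP of sterol genes, fell from 37.5 ± 1.62 to 24.0 ± 1.83 TPM (log2 -0.63, SE 0.07, limma adjusted p = 0.00392). INSIG1, a sterol-sensing retention protein, fell by 0.53 on the log2 scale, and SREBF1 by 0.50. Across these members the median was -0.25 (camera, Benjamini-Hochberg adjusted p = 1.57e-06), with adjusted p = 0.367 with an estimated correlation. SREBF1 kept its call in 3 of the 6 fits with a library left out, CYP51A1 in 4 and MSMO1 in 5, while SQLE, SREBF2 and INSIG1 kept theirs in all 6.

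Fatty acid synthesis and desaturation genes were also called lower as a list. Of 22 tested members, 5 fell, 0 rose and 17 did not pass. Adjusted over the list alone, 9 fell and 1 rose. SCD (ENSCAFG00845016649), which makes monounsaturated fatty acids, fell from 117 ± 0.326 to 82.6 ± 4.91 TPM (log2 -0.49, SE 0.05, limma adjusted p = 0.00342). ACSL3, an acyl-CoA synthetase, fell by 0.53 on the log2 scale, the fatty acid elongation enzyme HSD17B12 by 0.52 and the desaturase FADS2 by 0.47. The list median was -0.159 (camera, Benjamini-Hochberg adjusted p = 0.000557), with adjusted p = 0.439 with an estimated correlation. FADS2 kept its call in 2 and HSD17B12 in 3 of the 6 fits with a library left out.

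Glycolysis genes were not called as a list. Of 19 tested members, 1 rose, 0 fell and 18 did not pass, and 1 rose when adjusted over the list alone. The risen gene was ENO2, an enolase, from 1.12 ± 0.208 to 2.57 ± 0.474 TPM (log2 0.75, limma adjusted p = 0.0404), a low level, and its call was lost in each of the 6 fits with a library left out. HK2 was at 43.6 and 37.7 TPM, ALDOC at 22.5 and 26.3 TPM and PFKL at 32.4 and 35.7 TPM in control and treated cells, and none of these passed. Across these members the median was -0.00638, the mean 0.0454 and the test direction up (camera, Benjamini-Hochberg adjusted p = 0.713), so the signs differ. Of 18 tested lactate and pyruvate genes, 1 fell, 0 rose and 17 did not pass, and 2 fell when adjusted over the list alone. The fallen gene was BSG, the chaperone of lactate transporters, from 297 ± 14.9 to 246 ± 9.14 TPM (log2 -0.27, limma adjusted p = 0.0279), and it kept its call in 2 of the 6 fits with a library left out. PDK1, PDK2 and MPC1 had log2 differences of -0.23, 0.30 and -0.12 and did not pass. That list had a median of -0.0698 (camera, Benjamini-Hochberg adjusted p = 0.155).

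Genes that respond to glucose through MondoA and ChREBP were called higher as a list. Of 6 tested members, 1 rose, 0 fell and 5 did not pass, while 4 rose when adjusted over the list alone. TXNIP (ENSCAFG00845011435), which restrains glucose uptake, rose from 9.88 ± 0.713 to 17.9 ± 1.31 TPM (log2 0.79, SE 0.08, limma adjusted p = 0.00316). ARRDC4, ARRDC2 and HBP1 had log2 differences of 0.48, 0.30 and 0.22 and did not pass over all genes. Over the list the median was 0.262 (camera, Benjamini-Hochberg adjusted p = 0.00161), with adjusted p = 0.439 with an estimated correlation.

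The TCA cycle list and the nuclear-encoded respiratory chain list were called lower at the preset correlation. Of 20 tested TCA cycle genes, 0 rose or fell by limma over all genes, 8 fell at an unadjusted p under 0.05, and 1 fell when adjusted over the list alone. IDH2, IDH3G, SDHA and IDH1 had log2 differences of -0.21, -0.16, -0.15 and -0.28. The TCA list median was -0.0898 (camera, Benjamini-Hochberg adjusted p = 0.00055), with adjusted p = 0.439 with an estimated correlation and 0.0531 by fry. Of 46 tested nuclear-encoded respiratory chain genes, 3 fell, 0 rose and 43 did not pass, and 9 fell and 2 rose when adjusted over the list alone. NDUFC2 fell by 0.24 and NDUFA10 by 0.20 on the log2 scale, both complex I subunits, and the ATP synthase subunit ATP5MC2 by 0.18, while UQCRH was at 0.19 and did not pass. NDUFC2 and NDUFA10 lost their calls in each of the 6 fits with a library left out, and ATP5MC2 in all but 1. The respiratory list median was -0.0688 (camera, Benjamini-Hochberg adjusted p = 0.00308), with adjusted p = 0.367 with an estimated correlation, and quantile normalization ended the call (adjusted p = 0.110).

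Genes of the ATF4 amino acid stress response were called higher as a list. Of 28 tested members, 5 rose, 0 fell and 23 did not pass, and 5 rose when adjusted over the list alone. DDIT3 (ENSCAFG00845012093), a stress-induced transcription factor, rose from 21.9 ± 5.42 to 46.8 ± 3.38 TPM (log2 1.08, SE 0.15, limma adjusted p = 0.00916). SLC3A2, an amino acid transporter chain, rose by 0.48 on the log2 scale, the glutathione-degrading enzyme CHAC1 by 0.47 and NUPR1 by 0.40. The list median was 0.0651 (camera, Benjamini-Hochberg adjusted p = 0.00214), with adjusted p = 0.576 with an estimated correlation and 0.104 by fry. With 1 library left out it ran from 0.0437 to 0.118. CHAC1 kept its call in 3 and NUPR1 in 1 of the 6 fits with a library left out.

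The unfolded protein response list was called lower by camera and was not called by fry (adjusted p = 0.207). Of 20 tested members, 1 rose, 4 fell and 15 did not pass, and 2 rose and 7 fell when adjusted over the list alone. The chaperone HSP90B1 fell from 557 ± 18.9 to 453 ± 6.10 TPM (log2 -0.30), the disulfide isomerases PDIA4 and PDIA3 fell by 0.33 and 0.26 on the log2 scale, and HERPUD1, which acts in ER-associated degradation, rose by 0.45. The ER chaperone HSPA5, chosen after its value was seen, was at 455 and 506 TPM (log2 0.15) and did not pass over all genes (limma adjusted p = 0.108), while it rose when adjusted over the list alone. Over the list the median was -0.105 (camera, Benjamini-Hochberg adjusted p = 0.0103), with adjusted p = 0.657 with an estimated correlation. The call ended without control replicate 3 (adjusted p = 0.0647) and without (R)-GNE-140 replicate 3 (adjusted p = 0.0609), both by camera with Benjamini-Hochberg adjustment. PDIA3 kept its call in 1, PDIA4 in 2 and HSP90B1 in 5 of the 6 fits with a library left out.

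NRF2 targets, which answer oxidative stress, were called higher as a list. Of 18 tested members, 4 rose, 0 fell and 14 did not pass, while 8 rose when adjusted over the list alone. NQO1 (ENSCAFG00845009149), a quinone reductase, rose from 387 ± 16.2 to 493 ± 18.6 TPM (log2 0.35, SE 0.05, limma adjusted p = 0.00933). SLC7A11, the cystine transporter, rose by 0.45 on the log2 scale, the glutathione reductase GSR by 0.30 and PIR by 0.29. SLC7A11 is also a member of the ATF4 list. Across these members the median was 0.111 (camera, Benjamini-Hochberg adjusted p = 0.000135), with adjusted p = 0.469 with an estimated correlation. SLC7A11 and GSR lost their calls in each of the 6 fits with a library left out, and PIR kept its call in 2.

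Hypoxia response genes moved in both directions. Of 23 tested members, 1 rose, 2 fell and 20 did not pass, and 2 rose and 8 fell when adjusted over the list alone. ADM, a vasoactive peptide gene, fell from 522 ± 18.5 to 371 ± 5.59 TPM (log2 -0.49, limma adjusted p = 0.00223) and the oxygen sensor EGLN1 fell by 0.25 on the log2 scale, while the angiogenic factor VEGFA rose from 39.9 ± 0.780 to 52.3 ± 3.57 TPM (log2 0.38). P4HA2 was at log2 -0.30 and did not pass. The list median was -0.0638 (camera, Benjamini-Hochberg adjusted p = 0.0388), with adjusted p = 0.576 with an estimated correlation and 0.124 by fry. Without the filter on low values it was -0.032. The call ended without control replicate 2 (adjusted p = 0.0512), without (R)-GNE-140 replicate 2 (0.0939), with a mean TPM of at least 5 (0.0745), and under median-of-ratios (0.0630) and quantile scaling (0.102), all by camera with Benjamini-Hochberg adjustment. EGLN1 lost its call in each of the 6 fits with a library left out, and VEGFA kept its call in 2.

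**Figure D2:**
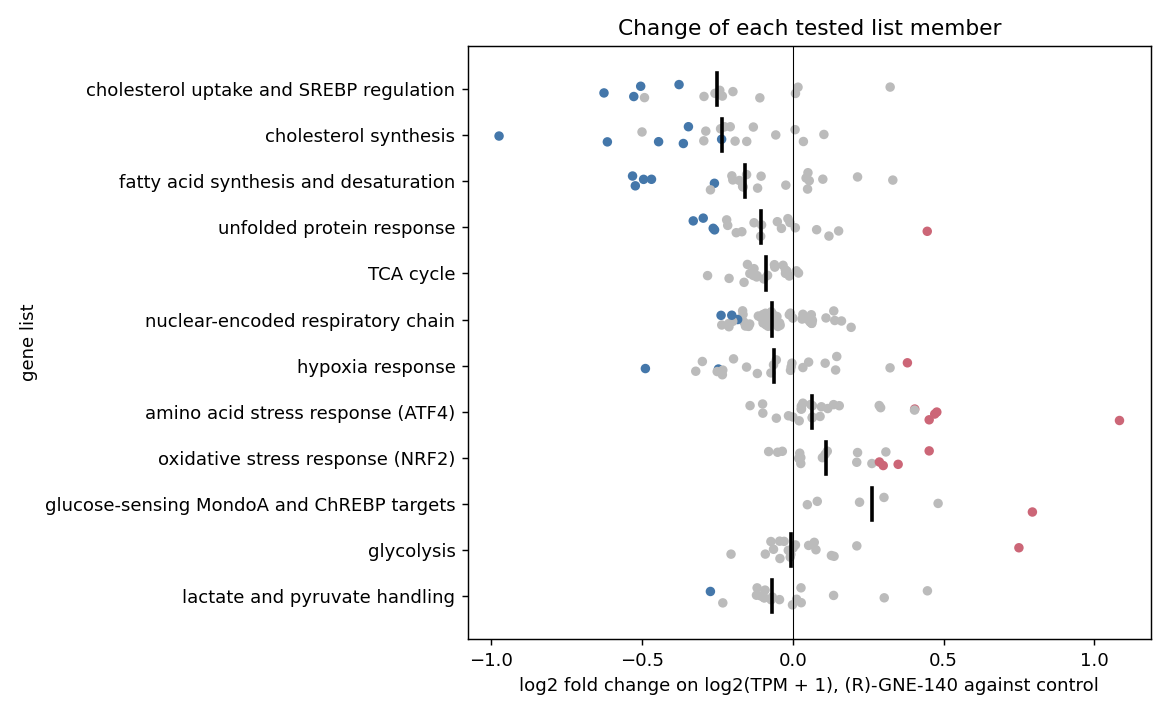
Log2 fold change of each tested member (x axis) of the 10 called lists and of glycolysis and lactate handling (y axis), with black lines at the list medians. Red points rose, blue points fell and grey points did not pass the limma test. The cholesterol synthesis median lies at -0.236 and the glycolysis median at -0.00638.

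The largest rise was in MMP1 (ENSCAFG00845000871), an interstitial collagenase, from 1.87 ± 0.0889 to 13.1 ± 2.77 TPM (log2 2.28, SE 0.14, limma adjusted p = 0.000168). The small heat shock proteins CRYAB and HSPB1 rose by 1.16 and 1.07 on the log2 scale, from 71.9 to 164 TPM and from 49.2 to 104 TPM. CYP1A1, a xenobiotic-metabolising cytochrome, rose from 3.07 to 7.29 TPM, the galectin LGALS3 from 11.4 to 24.5 TPM and DNER from 2.25 to 5.47 TPM. LOC119868937 and LOC100685649 held identical values in all 6 libraries (90.2 to 203 TPM), so they are not separate measurements, and LOC100686073 rose by 1.09 on the log2 scale. Among the falls, H2AC17, a histone gene, went from 14.4 to 7.38 TPM, MOSMO from 26.4 to 15.4, LOC102151856 from 13.8 to 7.94, MED26 from 29.9 to 17.9, NFE2L3 from 9.05 to 5.32 and the secreted chaperone CLU from 291 to 188 TPM, and SAPCD2 fell by 0.63 on the log2 scale. A row of LOC112656882 was listed at 15.92, 13.91 and 11.75 TPM in the controls and at 0 in all treated libraries. Without a single library, NFE2L3 lost its call in each of the 6 fits, MOSMO, SAPCD2 and DNER kept theirs in 1, MED26 in 3 and H2AC17 in 4.

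**Figure D3:**
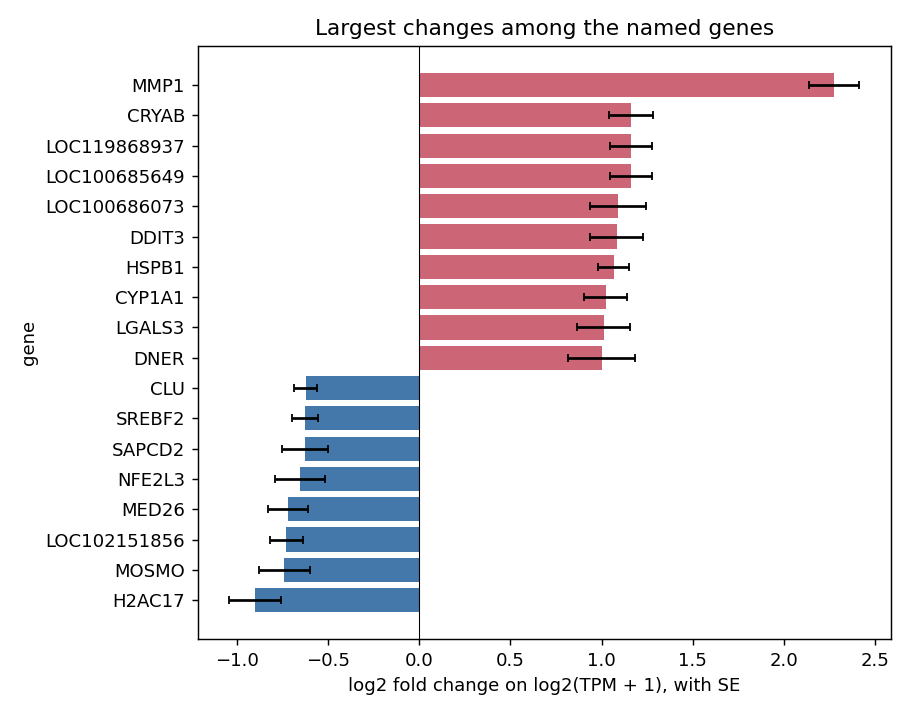
Log2 fold change on log2(TPM + 1) (x axis, bars with SE) of the named genes with the largest rises (red) and falls (blue), without LOC112656882. MMP1 reaches 2.28 and H2AC17 -0.90.

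The other 25 lists tested were not called by camera with Benjamini-Hochberg adjustment. Other lipid lists had few calls. The list of cholesterol efflux genes and LXR targets had a median of -0.0317 (9 tested, 1 fell, adjusted p = 0.569). Triglyceride and lipid droplet genes had -0.0156 (16 tested, 0 called, adjusted p = 0.946) and fatty acid oxidation genes 0.0115 (21 tested, 1 fell, adjusted p = 0.569). Adjusted over the list alone, 1 member of the efflux and LXR list and 1 oxidation gene fell, and 1 triglyceride gene rose and 1 fell. Pentose phosphate genes had a median of -0.0853 (9 tested, 0 called, 0 adjusted over the list alone, adjusted p = 0.0682) and glutamine and one-carbon genes 0.00363 (19 tested, 0 called, 0 adjusted over the list alone, adjusted p = 0.846). At an unadjusted limma p under 0.05, 2 triglyceride genes rose and 2 fell, 1 pentose phosphate gene fell, and 2 glutamine genes rose and 1 fell.

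Proliferation genes showed no call by limma over all genes. S-phase genes had a median of -0.0426 (31 tested, camera adjusted p = 0.449), mitosis genes -0.0457 (30 tested, 0.251), p53 targets 0.0249 (19 tested, 0.227) and apoptosis regulators -0.0309 (19 tested, 0.713), with 0 calls adjusted over the list alone in each. Unadjusted limma p values under 0.05 were found for 1 S-phase gene that rose and 2 that fell, 1 mitosis gene that fell, 4 p53 targets that rose and 1 apoptosis gene that fell. Among all genes tested, 1947 of 10874 had such a p, so these counts do not by themselves mark the lists. Interferon response genes had a median of 0.0609 (13 tested, camera adjusted p = 0.151), with 0 calls over all genes by limma and 3 that rose both at an unadjusted p under 0.05 and when adjusted over the list alone. In antigen presentation genes 1 of 11 fell, and 2 fell when adjusted over the list alone (median -0.0043, camera adjusted p = 0.557). In NF-kB and cytokine genes 1 of 14 rose, and 3 rose when adjusted over the list alone (median 0.0811, camera adjusted p = 0.209).

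In angiogenesis genes 2 of 20 rose and 1 fell, with 4 and 3 when adjusted over the list alone (median -0.0163, camera adjusted p = 0.846). In TGF-beta and matrix genes 2 of 18 rose, with 2 rising and 1 falling when adjusted over the list alone (median 0.0857, camera adjusted p = 0.151). YAP/TAZ targets had 0 calls over 17 genes and 1 that rose when adjusted over the list alone (median -0.0599, camera adjusted p = 0.704). Lysosome and autophagy genes had 1 rise and 2 falls among 26, with 2 and 4 when adjusted over the list alone (median -0.0444, camera adjusted p = 0.232). Of 55 ribosomal protein genes, 1 rose, and 5 rose when adjusted over the list alone (median 0.00329, camera adjusted p = 0.227). Heat shock genes had 2 rises among 12, also when adjusted over the list alone (median -0.00636, camera adjusted p = 0.451). Immediate early genes had 1 fall among 23, with 2 when adjusted over the list alone (median 0.055, camera adjusted p = 0.557). The median, the mean and the test differ in sign for fatty acid oxidation, glycolysis, glutamine, antigen presentation, angiogenesis, YAP/TAZ, heat shock and immediate early genes. The sign of the median also depended on the scaling for the glycolysis, antigen presentation, heat shock, immediate early and epithelial lists. With a mean TPM of at least 5 the immediate early median was -0.113, and on log2(TPM + 5) it was -0.00259. At an unadjusted limma p under 0.05, 2 YAP/TAZ targets rose and 2 fell.

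Of the cell type markers, 0 passed by limma over all genes. At an unadjusted p under 0.05, 1 endothelial marker rose and 6 fell, 3 fibroblast, 1 smooth muscle, 1 leukocyte and 1 erythroid marker rose, 1 epithelial marker fell and 0 adipocyte markers passed. The mean TPM was under 1 for 18 of 20 leukocyte, 8 of 10 epithelial, 8 of 9 erythroid, 9 of 12 smooth muscle, 9 of 16 fibroblast and 6 of 9 adipocyte markers matched. Endothelial markers, the lineage of this tumour, had a median of -0.076 over 22 genes, with 1 rise and 5 falls when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0749). Their median ran from -0.152 without (R)-GNE-140 replicate 1 to 0.000592 without (R)-GNE-140 replicate 2. Fibroblast and mesenchymal markers had a median of 0.339 over 7 tested genes, 0 of them called when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0771). The fibroblast median was 0.139 on log2(TPM + 5), 0.0739 without the filter on low values and -0.00846 with a mean TPM of at least 5. Smooth muscle markers (3 tested, median 0.172, camera adjusted p = 0.151) and adipocyte markers (3 tested, median 0.306, camera adjusted p = 0.108) had 0 calls either way. Leukocyte and epithelial lists had 2 tested members each and the erythroid list 1, too few for a list test. Adjusted over the list alone, 1 leukocyte and 1 erythroid marker rose and 1 epithelial marker fell. The mitochondrially encoded list is not analysed here.

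With a library left out, 7 of the uncalled lists passed by camera with Benjamini-Hochberg adjustment. Without control replicate 1, pentose phosphate (adjusted p = 0.0489) and fibroblast genes (0.0387) passed. Without control replicate 2, pentose phosphate (0.0284), ribosomal protein (0.0345) and endothelial genes (0.0284) passed, and without control replicate 3, TGF-beta (0.0213) and fibroblast genes (0.0427). Without (R)-GNE-140 replicate 1, pentose phosphate (0.0249), lysosome (0.0460), ribosomal protein (0.0460) and endothelial genes (0.00796) passed. Immediate early genes passed without (R)-GNE-140 replicate 2 (0.0284), and TGF-beta (0.0498), ribosomal protein (0.0455) and fibroblast genes (0.0407) without replicate 3.

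Over the 17 alternatives run with camera, fits with a library left out included, the medians of the called lists kept their sign. They ran from -0.26 to -0.206 for cholesterol synthesis, -0.273 to -0.215 for cholesterol uptake, -0.186 to -0.115 for fatty acid synthesis, 0.2 to 0.298 for MondoA and ChREBP targets, -0.101 to -0.0705 for the TCA cycle, -0.0796 to -0.0453 for the respiratory chain, 0.0437 to 0.118 for ATF4, -0.142 to -0.0719 for the unfolded protein response, 0.104 to 0.133 for NRF2 and -0.0832 to -0.032 for hypoxia. Among uncalled lists the sign was also kept by NF-kB (0.00834 to 0.153), TGF-beta (0.0409 to 0.206), interferon (0.0158 to 0.108), p53 (0.0137 to 0.0694), mitosis (-0.0544 to -0.0152), pentose phosphate (-0.134 to -0.0603) and lactate genes (-0.0717 to -0.0498). Smooth muscle (0.12 to 0.228) and adipocyte markers (0.139 to 0.545) kept it in the 15 alternatives that tested them. The sign changed for glycolysis (-0.0313 to 0.0298), efflux (-0.11 to 0.0646), triglyceride (-0.0685 to 0.0373), fatty acid oxidation (-0.0307 to 0.0228), glutamine (-0.02 to 0.029), S-phase (-0.0487 to 0.0065), apoptosis (-0.0321 to 0.0145), antigen presentation (-0.084 to 0.087), angiogenesis (-0.0527 to 0.0233), YAP/TAZ (-0.0679 to 0.000189), lysosome (-0.0625 to 0.00382), ribosomal protein (-0.0134 to 0.0175), heat shock (-0.0271 to 0.0336), immediate early (-0.161 to 0.15), endothelial (-0.152 to 0.000592) and fibroblast genes (-0.00846 to 0.427).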

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

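Leaving out rows with repeated values, an alternative chosen after seeing the data, gave 330 changed genes. All genes called in the reported test kept their direction in every alternative in which they were tested. The count of changed genes was 168 (80 higher, 88 lower) with no filter and 159 (92 higher, 67 lower) with no variance trend, and 74 to 185 (32 to 84 higher, 41 to 124 lower) with 1 library left out, where fewer samples enter the test. With the replicate block it was 163 (67 higher, 96 lower). With 1 library left out, the higher genes made up from 33% of the changed genes (without control replicate 2) to 55.4% (without control replicate 1). Without the variance trend they made up 57.9%, against 43.2% as reported. Deviations from the group means of same-numbered libraries correlated at r = 0.0358, 0.00927 and -0.0977, and not every library correlated best with its own number. This gives no sign that the numbers pair the samples, but 3 libraries per group cannot exclude it. Under the block the hypoxia list lost its call (adjusted p = 0.0550) and the endothelial list gained one (0.0314), both by camera with Benjamini-Hochberg adjustment. The other alternatives gave 325 to 440. Of 48 named genes called, 21 kept their call in each of the 6 fits with a library left out. Depth is unknown, so what it limits cannot be given.

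Of 10 lists called, 0 were called with an estimated correlation and 6 by fry, which lost the TCA cycle, ATF4, hypoxia and unfolded protein lists. Among the 6, the fatty acid synthesis, MondoA and ChREBP, and NRF2 lists lay at the threshold, with a fry adjusted p that rounds to 0.05. Cholesterol synthesis, cholesterol uptake and the respiratory chain each had a fry adjusted p of 0.0286. The respiratory chain had an estimated correlation of 0.012, close to the preset 0.01, yet its unadjusted camera p went from 0.000703 to 0.0303. A call lost with the estimated correlation therefore does not by itself show that correlation between genes undid it. With the estimated correlation the camera adjusted p was 0.367 for cholesterol synthesis, 0.367 for cholesterol uptake and 0.439 for fatty acid synthesis. Over the 17 other camera fits these lists stayed called, with adjusted p up to 8.47e-08, 1.27e-05 and 0.00213. LDHB reversed to 0.0604 under quantile normalization and 0.0109 with the 20 most abundant genes removed, and was -0.016 to 0.0239 with 1 library left out, with 0.0233 the other value above 0. Uncalled lists that reversed did so without passing, with these camera adjusted p: triglyceride 0.442 (no filter), 0.987 (mean TPM of at least 5) and 0.997 (block), efflux 0.840 (no filter), angiogenesis 0.903 (mean TPM of at least 5) and glutamine 0.643 (quantile). With 1 library left out, lists that reversed in some of the 6 fits had camera adjusted p of 0.614 to 0.991 (triglyceride), 0.614 to 0.945 (angiogenesis), 0.509 to 0.957 (glutamine), 0.509 to 0.911 (YAP/TAZ), 0.0284 to 0.991 (immediate early), 0.290 to 0.999 (glycolysis) and 0.0345 to 0.644 (ribosomal proteins). The fits that passed kept the reported direction. In alternatives that kept all 6 libraries, 5 uncalled lists passed in at least 1 (pentose phosphate, endothelial, smooth muscle, adipocyte and fibroblast). With 1 library left out the medians of the called lists kept their sign, from -0.26 to -0.225 for cholesterol synthesis, -0.273 to -0.233 for cholesterol uptake, -0.186 to -0.115 for fatty acid synthesis and -0.0796 to -0.0453 for the respiratory chain, while the medians of the S-phase, YAP/TAZ, angiogenesis, antigen presentation, apoptosis, efflux, ribosomal protein, endothelial, fatty acid oxidation, glutamine, glycolysis, heat shock, immediate early, lysosome and triglyceride lists changed sign in at least 1 fit. The cause was not tested.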

Other observations

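The tests of scaling, expression level and member signs for the cholesterol list, of heat shock and of other splits, and the spread set beside the ATF4 scaling test, were chosen only after the result was seen, as were the added gene lists below. An added list of secretory pathway genes was lower after (R)-GNE-140 at the preset correlation. A list of translocation, glycosylation and vesicle transport genes was written after falls in single ER genes such as SEC11C (log2 -0.55) and CNIH4 (log2 -0.55) had been seen. ERGIC1, seen before the list was written, was left out. Of the 58 other tested members 13 fell and 0 rose, and 24 fell when adjusted over the list alone. The oligosaccharyltransferase subunits STT3B and RPN2 fell by 0.37 and 0.32 on the log2 scale, the translocon-associated SSR2 by 0.32 and the cargo receptor TMED3 by 0.47, all chosen after their values were seen. The median was -0.11, and -0.11 to -0.0833 under the other scalings, with a camera p of 1.2e-10 against other genes (limma, Benjamini-Hochberg adjusted p = 6e-10 over the 5 added list tests). With an estimated correlation the camera p was 0.109, which is not adjusted. The unadjusted camera p of the cholesterol synthesis list with an estimated correlation was 0.0158. The list was lower as a group, but it was written after single ER falls were seen in these same libraries. Its test therefore cannot show independently that a group drop accounts for them, and it holds only at the preset correlation.

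PLAU, the urokinase, chosen after its value was seen, rose by limma from 92.2 ± 2.85 to 118 ± 6.20 TPM (log2 0.35, n = 3 in each group). IL18R1, a cytokine receptor chain also chosen after its value was seen, rose by limma from 0.71 ± 0.121 to 3.48 ± 0.677 TPM (log2 1.38).

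The fall of the cholesterol synthesis list was weighed against scaling, expression level and a few members. A factor common to all genes would move all genes alike, and the median over all genes was 0.00403 against -0.236 for the list. Quantile normalization, which moves genes unequally, left the list at -0.215 (camera adjusted p = 1.41e-08). Of 10000 random lists matched on mean expression, 0 had a median as low (percentile 0, lowest random median -0.149). The random lists hold unrelated genes, so they test expression level and not variation shared between members of a pathway. The 13 members not called on their own were still lower than other genes with a camera p of 0.000205 (limma, Benjamini-Hochberg adjusted p = 0.000512), and 16 of all 19 members lay below 0, and 49 of the 10000 random lists had as many or more below 0. These values argue against each explanation tested as the whole cause, and an effect of (R)-GNE-140 on these transcripts stays open as a hypothesis. The list's call is lost with an estimated correlation. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) called as many as 329 genes and the highest other called 1, but 10 splits are too few for a share under 0.05. Each other split also mixes control and treated libraries, so a difference between the groups would add to its spread and lower its count. Those counts therefore do not show what chance alone would give.

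The ATF4 list was called higher and the unfolded protein list lower by camera, and neither was called by fry. Without DDIT3 the ATF4 list kept a camera p of 0.00186 (limma, Benjamini-Hochberg adjusted p = 0.00233), which argues against that gene as the whole cause. A factor common to all genes of a library cannot open a gap between lists, so of the scalings only quantile normalization tests this. Under it the medians were 0.0767 and -0.0937, a gap of 0.17 (log2), and the mean difference between the lists changed by 0.218, with an SD of 0.0515 among controls and 0.0196 among treated libraries (n = 3 each), which argues against scaling as the whole cause. An effect of (R)-GNE-140 stays open as a hypothesis, and with an estimated correlation neither list was called.

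The row of LOC112656882 at 0 in treated libraries is 1 of 4 rows of that symbol. Summed over the rows, TPM was 18.9 ± 8.31 in controls and 6.6 ± 6.58 in treated libraries (SD, n = 3), a change of -1.47 control SDs. This lies between the bounds set for and against reads moving between copies, so the loss of the transcript and such a move cannot be told apart. Another row of the symbol was at 0 in all controls and at 6.64, 0 and 13.16 TPM in treated replicates 1, 2 and 3. In treated replicate 2 all 4 rows were at 0, so there the TPM did not appear in another row of this symbol. The control SD rests largely on a row at 12.53 TPM in control replicate 1 and 0 in the other controls.

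A rise of aryl hydrocarbon receptor targets was tested for the rise of CYP1A1. The other 7 tested targets had a median of 0.147 (SD 0.121), and 1 of them, NQO1, rose, which the NRF2 list also holds. They were higher than other genes at the preset correlation (camera in limma, Benjamini-Hochberg adjusted p = 0.0021), with an unadjusted p of 0.124 with an estimated correlation. The bound written beforehand against the hypothesis, a median below 0.2 with fewer than 2 targets passing, was met, but by less than the SD of the targets. The margin of an SD was added after the value was seen, and this SD is the spread between genes, not an error of their median. By the rule as first written the result goes against a group rise. The camera call at the preset correlation goes the other way, so the question is left open. A heat shock response was tested for the rise of HSPB1 and CRYAB. Without HSPB1 the heat shock list had a median of -0.0255 over 11 tested genes (SD 0.116), of which 1 rose. The list did not differ from other genes past the threshold (camera in limma, Benjamini-Hochberg adjusted p = 0.975). The median lies below the bound of 0.1, which argues against a rise of the whole list. It does so by more than the SD, but this margin too was added after the value was seen. Here as well the SD is the spread between genes, not an error of their median.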
